A study of Mus musculus with 4 samples.

How the data were processed

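Transcripts were measured with the Visium assay, which captures RNA on an array of barcoded spots, in formalin-fixed paraffin-embedded (FFPE) mouse liver sections. There were 4 sections, each from a separate mouse as the series' design text names them. They fell into 3 groups: 1 healthy section, 2 fibrotic sections and 1 fibrotic section with Hk2 deleted. Per the file headers, the authors made the deposited count matrices with Space Ranger 2.0.0, and the values are UMI counts per gene and spot. The genome was mm10 per the submitters' processing notes. The probe set and the other settings are not given in the sources used here. The authors also deposited a table per section with a spatial score, Moran's I, for each gene, and its adjusted p-value per the file headers; the p-value was not used here. The UMI totals per gene in that deposited table were checked against the matrices and were equal for all genes listed in each section.

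The matrices held 19465 genes, and all deposited spots lay over tissue. Section totals ranged from 40585039 to 67479047 UMIs. Exact Poisson intervals with a confidence of 95% were computed for levels of single sections; they cover counting error only, and UMIs of 1 section are not replicates. Images were not analysed here. Spots hold several cells, so no spot was assigned to a cell type.

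For whole-section comparisons, counts were summed over all spots of a section, since spots are not replicates. edgeR 4.0.16 in R 4.3.3 was used with TMM scaling, the filterByExpr filter on low counts and the quasi-likelihood test. A single fit of 3 groups gave the contrast of fibrotic with healthy and that of Hk2-deleted fibrotic with fibrotic. The fibrotic sections give the only residual degree of freedom, so the lone healthy and Hk2-deleted sections were assumed to vary like them. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Values per section are raw CPM (a gene's UMIs scaled to the section's total in the usual unit) where given with intervals, and fold changes are on the log2 scale with their standard error (SE).

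Liver lobules are zoned from the portal to the central vein. Each spot was scored within its section as the mean z of log2(CPM + 1) of 9 pericentral landmarks minus that of 12 periportal landmarks. Spots were split by score into 3 equal parts, and counts of the top (pericentral) and bottom (periportal) parts were summed, with section as a block. A zone by group term tested whether the difference between zones differed between CCl4 and olive oil. The 21 landmarks were left out of the counts of calls there. Collagen-high spots were the 10 percent of spots of a section with the highest share of Col1a1, Col1a2 and Col3a1 UMIs. In the 3 CCl4-treated sections they were compared with all other spots, with section as a block. A spot kind by genotype term tested the difference with Hk2 deletion, and the 3 collagen genes were left out of the counts of calls.

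The 22 gene lists were fibrillar collagen, other extracellular matrix and crosslinking, stellate cell and contractile, glycolysis, hepatocyte glucose metabolism, extracellular vesicle biogenesis and release, pericentral landmarks, periportal landmarks, other pericentral hepatocyte genes, other periportal hepatocyte genes, cytochrome P450, macrophage, lymphocyte and neutrophil, endothelial, cholangiocyte and ductular, proliferation, oxidative and p53 stress, acute phase, lipogenesis and sterol synthesis, fatty acid oxidation, hypoxia response, and tissue or blood other than liver parenchyma. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry; lists with under 5 tested members got no set test. Camera compares a list with the other genes, while fry asks whether its members move, on balance, one way. With an estimated correlation, camera tests on the residual degrees of freedom of the fit. These were 1 in the whole-section and interaction fits, 2 for collagen-high spots and 3 between zones. It could thus hardly call any list, and a call lost there does not argue against a list. Calls at the preset correlation rest on that assumed value. Named genes followed a rule. Hk2 came first, then the 8 largest increases and the 8 largest decreases per comparison among called genes with a pooled CPM of at least 10. In whole-section comparisons the lone section also had to lie outside the range of the 2 fibrotic sections, and in zone and collagen comparisons the sign had to match in every section fitted. For the 2 interaction terms, the lone section's log2 ratio had to lie outside the range of the fibrotic ones. Then came up to 4 called members per list with the largest change, or up to 2 members with the highest mean CPM where none was called. Hk1, Hk2, Hk3, Pdgfrb, Acta2, Col1a1, Timp1, Cyp2e1, Glul and Cyp2f2 could be named anywhere, but Glul was not among the genes of the matrices. Nor were Tpi1, Eno1 and Ldha of the glycolysis list and Saa1 and Saa2 of the acute phase list. The vesicle list lacked Vps4a, Vps25, Chmp2a, Snap23 and Vamp7, and some other lists lacked members as well. Some genes that the rule names are not reported here. The comparisons, tests, lists, this rule and most alternative settings were chosen before the data were examined.

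Spot correlations of list shares (Spearman) were computed in each section after thinning spots to 9388 UMIs, and shallower spots were left out. Each was set against 1000 random lists matched on mean expression. List levels were also computed by array steps from the nearest collagen-high spot. For the agreement of the whole-section contrasts across genes, 100 simulations over the same fibrotic libraries gave the value that the shared sections produce when neither CCl4 nor Hk2 deletion has an effect.

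The fits were tested on simulated data with the same layouts. Counts were drawn with the dispersion estimated from the real counts of that comparison, and with no further differences between sections. The shares of false calls thus cannot show whether that dispersion is too small for real mice. For CCl4 against olive oil, 40% of genes set to a log2 fold change of 1 and 84.2% of those set to 2 were called, and 9.09% of calls were false. For Hk2 deletion against CCl4 control these values were 44.4%, 92% and 4.9%. Pericentral against periportal spots gave 94.9%, 99% and 5.91%, and zonation under CCl4 gave 64.6%, 86.9% and 2.6%. Collagen-high against other spots gave 90.7%, 93.9% and 0.549%, and collagen-high spots with Hk2 deletion gave 60.4%, 82.5% and 5.48%.

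Alternatives covered RLE size factors, no filter on low counts, DESeq2 1.42.0, leaving out spots with few UMIs (under 0.5 of the section's median), thinning all sections to 40585039 UMIs, equal weight per spot with limma, other zone splits and scores, 5 or 20 percent of spots as collagen-high, and leaving out sections in turn. Added after seeing the data were comparisons without the section lacking Y-linked transcripts, all 3 CCl4-treated sections against healthy for the whole-section contrast, and fits without spots of high local Saa3 share or near Msln or Upk3b UMIs. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for spot values and plots.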

Results

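Spatial transcript levels were measured in 4 mouse liver sections to ask how carbon tetrachloride (CCl4), a hepatotoxin that injures pericentral hepatocytes, and deletion of Hk2 (hexokinase 2, which phosphorylates glucose in the first step of glycolysis) change the liver in space. The healthy section (n = 1) and the fibrotic sections (n = 2) came from Hk2-floxed mice given olive oil or CCl4. The Hk2-deleted fibrotic section (n = 1) came from a CCl4-treated mouse with a tamoxifen-inducible Cre under the Pdgfrb promoter, which is active in hepatic stellate cells, the main collagen-producing cells of fibrosis. The labels give males aged 5 months, tamoxifen at 75 mg/kg for 5 days, a wait of 2 weeks, and CCl4 at 1 µL/g injected 2 times a week. The design text gives 6 weeks of CCl4, while the sample protocol gives 4 or 6 weeks. The healthy section had 3064 spots and 54031683 UMIs, and fibrotic replicate 1 had 4134 spots and 67479047 UMIs. Fibrotic replicate 2 had 2577 spots and 40585039 UMIs, and the Hk2-deleted section 3865 spots and 65179106 UMIs. Median UMIs per spot ran from 13665 to 15588. Albumin (Alb) took 13.5% of UMIs in the healthy section, 12.3% and 10.1% in the fibrotic sections, and 6.88% in the Hk2-deleted section.

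Hk2 (ENSMUSG00000000628, chromosome 6, positions 82725025 to 82774454 of GRCm38.p6) was detected in every section, the Hk2-deleted one included. Its level was 1.85 CPM (exact Poisson 95% interval 1.51 to 2.25) in the healthy section. The fibrotic sections had 4.88 CPM (4.36 to 5.43) and 3.94 CPM (3.36 to 4.60), and the Hk2-deleted section had 3.50 CPM (3.06 to 3.98), from 100, 329, 160 and 228 UMIs in this order. The log2 fold change was 0.91 ± 0.34 (SE, adjusted p = 0.0847) with CCl4 and -0.38 ± 0.33 (adjusted p = 1.00) with Hk2 deletion, so neither passed. The part of Hk2 that the probes read and the part that was deleted are not given in the sources used here. A probe outside the deleted part checks nothing, and section totals also count cells in which the Cre is not active. Among the other hexokinases, Hk1 was 0.56 ± 0.20 (adjusted p = 0.0709) and Hk3 0.54 ± 0.20 (adjusted p = 0.0844) with CCl4 on the log2 scale. Their UMI totals were close in every section, 541 and 540 in the healthy one and 1456 and 1441 in fibrotic replicate 1. Fibrotic replicate 1 stood apart in Y-linked transcripts. Eif2s3y was at 0.578 CPM there against 69.9, 62.1 and 63.2 CPM in the healthy, fibrotic replicate 2 and Hk2-deleted sections, and Ddx3y was at 0.415 against 52.4, 50.3 and 47.0 CPM.

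**Figure D1:**
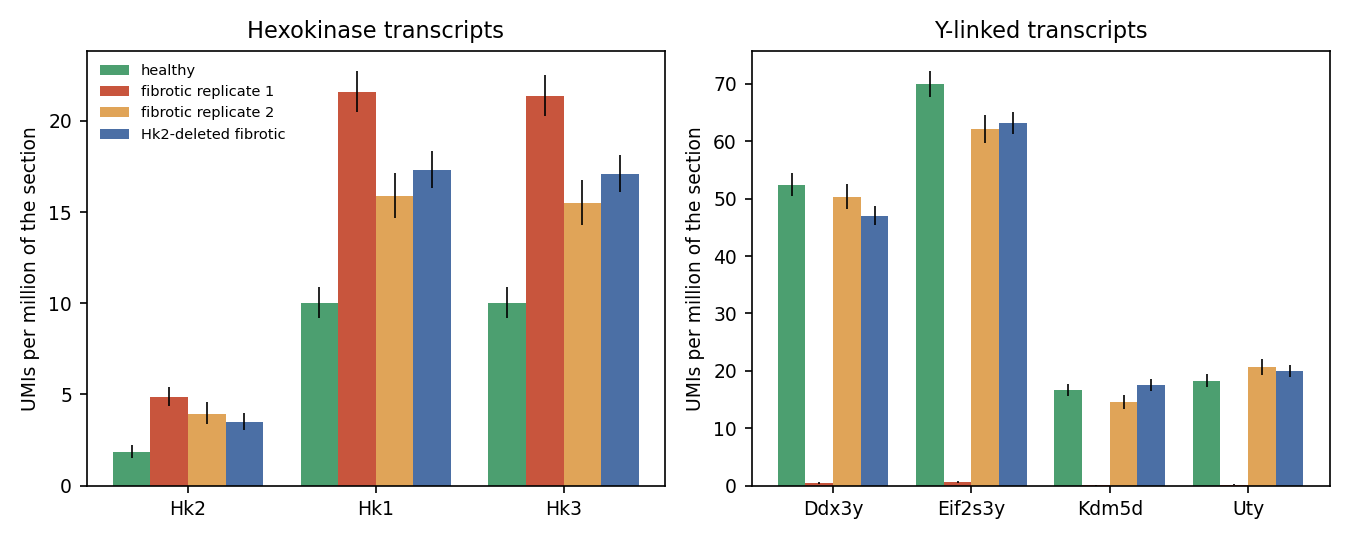
Raw CPM (vertical axes) of 3 hexokinase genes (left) and 4 Y-linked genes (right), with a bar per section and exact Poisson 95% intervals as error bars. Hk2 lies between 1.85 and 4.88 CPM in all sections, and the Y-linked genes are near 0 in fibrotic replicate 1 alone.

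CCl4 against olive oil asks what the injury did to the whole tissue. Fibrillar collagen transcripts rose: Col1a1 by 4.79 ± 0.44 log2 (adjusted p = 5.4e-07), Col1a2 by 3.91 ± 0.44 and Col3a1 by 3.46 ± 0.42. The largest increases included Ltf (lactoferrin, 9.03 ± 0.56) and Camp (cathelicidin, 7.40 ± 0.39), both stored in neutrophil granules, Ngp (7.22 ± 0.43), Retnlg (5.16 ± 0.54), S100a9 (4.99 ± 0.51) and S100a8 (4.98 ± 0.45). Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, rose by 8.58 ± 0.37 and Mmp12, the macrophage elastase, by 5.66 ± 0.53. In the healthy section Ltf was at 0.0889, Gpnmb at 0.222 and Camp at 0.333 normalised CPM. The sizes of these rises thus rest on few UMIs in the healthy section. The largest decreases included Mup11 (a major urinary protein, -8.83 ± 0.41), the organic anion transporter Slco1a1 (-5.54 ± 0.43), Susd4 (-5.02 ± 0.23), Fitm1 (-4.56 ± 0.29), the glycogen-targeting subunit Ppp1r3g (-3.13 ± 0.32) and Selenbp2 (-2.84 ± 0.26). The pericentral enzymes and transporters Oat (-2.82 ± 0.31) and Slc1a2 (-2.73 ± 0.21) fell too.

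Of 36 other extracellular matrix genes, 33 rose and none fell (33 adjusted over the list alone), with a median of 1.91 log2. Ltbp2 rose by 5.17, Mmp2 by 3.91, Mmp13 by 3.22 and Timp1, an inhibitor of matrix proteases, by 2.76 ± 0.65 (adjusted p = 0.007). All 3 fibrillar collagens rose. In the stellate cell and contractile list 11 of 24 rose (13 adjusted over the list alone), including Pdgfrb (1.58 ± 0.21), Pdgfra (1.92) and Vim (1.76), while the contractile actin Acta2 was at 0.52 ± 0.28 (adjusted p = 0.252; 0.02 without fibrotic replicate 1 and 0.86 without replicate 2). The macrophage list had 13 of 24 higher and 1 lower (17 and 2 adjusted over the list alone), with Trem2 at 4.06, Cx3cr1 at 3.31 and Ccr2 at 2.21. Lymphocyte and neutrophil genes had 11 of 24 higher (13 adjusted over the list alone), proliferation genes 17 of 24 (18 adjusted over the list alone; Mki67 2.66, Plk1 2.78), and cholangiocyte genes 6 of 14 (10 adjusted over the list alone; Epcam 1.52, Krt19 1.57, Cd24a 1.91). The matrix, stellate, macrophage, lymphocyte, proliferation and cholangiocyte lists stood above other genes by camera (adjusted p from 2.4e-41 to 4.3e-06). None kept that call (adjusted p = 0.562 with an estimated correlation for all 6), but with 1 residual degree of freedom that test could hardly call any list. Among markers of other tissue or blood, 3 of 9 rose (3 adjusted over the list alone): the transcription factor Wt1 (2.83), haemoglobin Hbb-bt (1.37) and platelet factor Pf4 (0.83). For this list camera gave adjusted p = 0.0253, and adjusted p = 0.662 with an estimated correlation.

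The glycolysis list had 3 of 17 members higher and 1 lower (6 and 2 adjusted over the list alone), with a median of 0.16 and a camera adjusted p of 0.508. Pyruvate kinase Pkm rose by 0.85, phosphofructokinase Pfkp by 0.77 and the lactate exporter Slc16a3 by 1.56, while Pfkfb3, which makes an activator of phosphofructokinase, fell (-1.36). Of 38 extracellular vesicle genes 3 rose and 1 fell (the same counts adjusted over the list alone). The tetraspanins Cd63 (3.20) and Cd9 (1.27) and the sphingomyelinase Smpd3 (2.70) were higher, and Hgs (-0.71), a sorting protein of multivesicular bodies, lower. The vesicle list's median was -0.09 but its mean 0.11, with a camera adjusted p of 0.869. Without fibrotic replicate 1 the glycolysis and vesicle medians were 0.26 and 0.0028, and without replicate 2 they were 0.10 and -0.21. Hepatocyte glucose metabolism had 4 of 14 lower (5 adjusted over the list alone), with Ppp1r3c at -0.95, glycogen synthase Gys2 at -0.83 and Ppp1r3b at -0.76. Lipogenesis and sterol synthesis had 5 of 16 lower (8 adjusted over the list alone), among them Fasn (-1.56), Lss (-1.20) and Acly (-1.19), and fatty acid oxidation 1 of 16 (1 adjusted over the list alone), Fabp1 (-1.55). Cytochrome P450 genes had 2 of 19 higher and 3 lower (2 and 6 adjusted over the list alone), with Cyp7b1 (-2.56) and Cyp8b1 (-2.50), both of bile acid synthesis, lower and Cyp17a1 (1.36) higher. Glucose metabolism, lipogenesis, fatty acid oxidation and cytochrome P450 lists lay below other genes by camera (adjusted p from 2.0e-06 to 0.0076), and none kept the call (adjusted p of 0.562 to 0.566 with an estimated correlation).

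Among the remaining lists, pericentral landmarks had 2 of 9 higher and 2 lower (the same adjusted over the list alone), with a camera adjusted p of 0.0025 and adjusted p = 0.562 with an estimated correlation. Axin2 (1.30) and Rhbg (1.31) were higher, Oat and Slc1a2 lower. Periportal landmarks had 2 of 12 higher (2 adjusted over the list alone), Aldh1b1 (1.49) and Ctsc (0.95), against a median of -0.24. Other pericentral genes had 1 of 22 higher, Gstm3 (2.44), and 2 lower, Slc22a3 (-4.58) and Car3 (-1.66), and other periportal genes had 3 of 22 higher, Apoa4 (2.75), Cyp17a1 and Cdh1 (0.64), with the same counts adjusted over each list alone. Endothelial genes had 2 of 24 higher, Lyve1 (2.19) and Cd34 (2.19), and 1 lower, Ehd3 (-0.91). Stress genes had 4 of 19 higher and 1 lower (5 and 1 adjusted over the list alone), the p53 targets Cdkn1a (2.33), Phlda3 (2.21) and Eda2r (2.56) among the former and Trib3 (-1.46) the latter. Acute phase genes had 2 of 15 higher, the siderophore-binding Lcn2 (3.64) and the orosomucoid Orm2 (2.44), and 1 lower, Socs3 (-1.23). Hypoxia genes had 1 of 14 lower, Ddit4 (-1.27). Adjusted over the list alone, the endothelial, acute phase and hypoxia counts were the same, and camera gave none of the periportal, other zonal, endothelial, stress, acute phase or hypoxia lists an adjusted p under 0.05. The other periportal list had a median of -0.15 and a mean of 0.07, and the acute phase list a median of 0.05 and a mean of 0.21 but a downward camera test.

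In all, 1362 genes rose and 567 fell of 14125 tested. DESeq2 called 729 and 295, equal weight per spot with limma called 204 genes lower, and the contrast rests on 1 healthy section. Cdh1, Cyp7b1, Ddit4, Hbb-bt, Hgs, Krt19, Orm2, Pf4, Pfkp, Ppp1r3c, Ppp1r3g and Slc16a3 were not called by DESeq2. With fibrotic replicate 2 and the Hk2-deleted section, the CCl4-treated sections with Y-linked transcripts, in place of both fibrotic ones, 1191 genes rose and 686 fell, of which 1080 and 477 were also called with the fibrotic sections. Cdh1, Cldn4, Cyp17a1, Hbb-bt, Krt19, Pf4, Pfkp, Ppp1r3b, Ppp1r3c, Slc16a3 and Socs3 were not called with those sections. Without fibrotic replicate 1, Ddit4 was at -0.78, Hbb-bt at 0.67, Krt19 at 1.01 and Ppp1r3c at -1.74, and without replicate 2, Ddit4 was at -1.97, Cyp7b1 at -3.98, Orm2 at 1.2 and Ppp1r3c at -0.48.

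**Figure D2:**
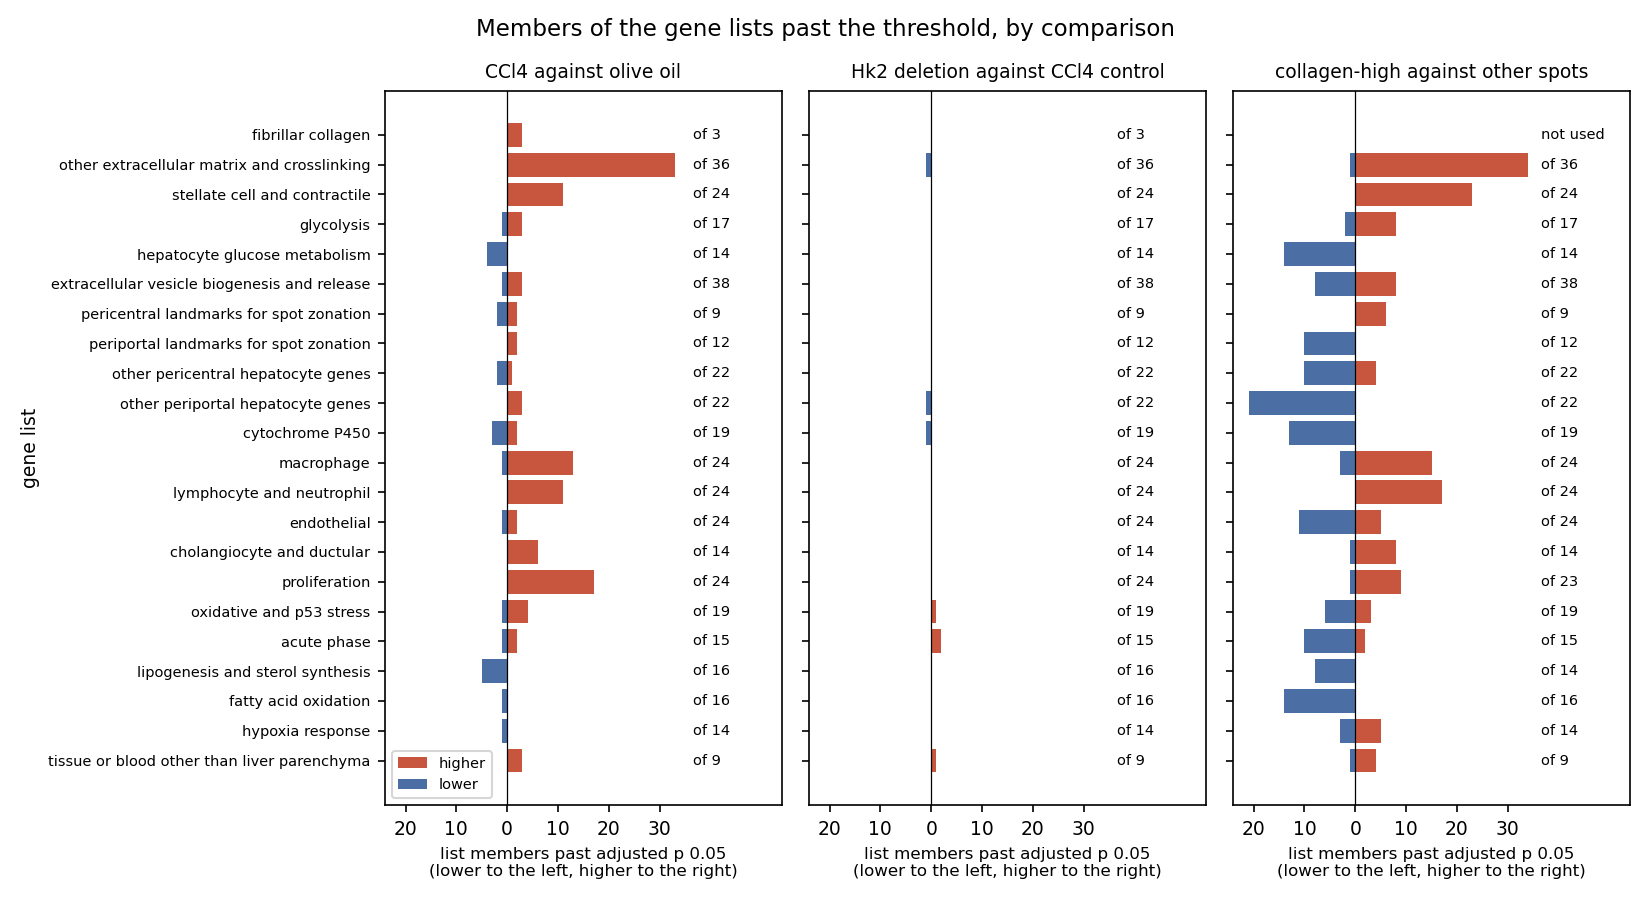
Numbers of list members past the adjusted p threshold of 0.05 (horizontal axes, higher to the right and lower to the left) for each gene list (vertical axis) in 3 comparisons, with the number of tested members beside each bar. Extracellular matrix members were higher in 33 of 36 cases with CCl4 and in 34 of 36 in collagen-high spots, and few members of any list passed with Hk2 deletion.

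Hk2 deletion against CCl4 control asks how fibrotic tissue differed with the Cre meant to delete Hk2 in Pdgfrb-expressing cells. Higher in the Hk2-deleted section (n = 1) than in both fibrotic sections (n = 2) were the serum amyloid Saa3 by 3.50 ± 0.47 log2 (adjusted p = 0.0013), Lcn2 by 2.1 ± 0.37 (adjusted p = 0.012) and the neutrophil chemokine Cxcl1 by 1.97 ± 0.20 (adjusted p = 6.3e-05). Metallothionein Mt2 (2.08 ± 0.42), Angptl8 (1.90 ± 0.33), a regulator of lipoprotein lipase, the repressor Bcl6 (1.83 ± 0.21), Orm3 (1.66 ± 0.27) and Isyna1 (1.46 ± 0.17), an inositol synthase, rose as well. Lower were immunoglobulin Ighg2c (-2.18 ± 0.39), Ppp1r3g (-2.06 ± 0.39), Cish (-1.92 ± 0.26), an inhibitor of cytokine signalling, Mmp12 (-1.89 ± 0.39), Rgs1 (-1.68 ± 0.29), Serpina12 (-1.61 ± 0.26), Ces2c (-1.26 ± 0.19) and Cyp17a1 (-1.16 ± 0.19). Collagen did not pass: Col1a1 was at -0.15 ± 0.34, Timp1 at 0.99 ± 0.47 and Pdgfrb at -0.24 ± 0.19 (adjusted p = 1.00 each), and Acta2 was at 0.96 ± 0.26 (adjusted p = 0.290). These values depended on the section: without fibrotic replicate 1, Col1a1 was at 0.48, Pdgfrb at -0.04 and Acta2 at 1.46, and without replicate 2, Col1a1 was at -0.58, Pdgfrb at -0.40 and Acta2 at 0.61.

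Of 15 acute phase genes, 2 rose (6 adjusted over the list alone) and all 15 had a positive fold change, with a median of 1.00 log2. For this list camera gave adjusted p = 2.5e-57, and adjusted p = 0.919 with an estimated correlation. Of 17 glycolysis genes none passed either way, 16 had a negative fold change and the median was -0.16 (camera adjusted p = 0.0364; adjusted p = 0.919 with an estimated correlation). The cytochrome P450 list (1 of 19 lower, Cyp17a1; camera adjusted p = 2.6e-05), the other periportal list (1 of 22 lower; camera adjusted p = 0.0364) and the macrophage list (0 of 24; camera adjusted p = 0.0105) lay below other genes, each with adjusted p = 0.919 with an estimated correlation. Adjusted over the list alone, these counts were the same. In the other extracellular matrix list 1 of 36 fell, Mmp12 (2 adjusted over the list alone). Its median of -0.06 was -0.29 or 0.19 with 1 fibrotic section left out, and -0.32 without spots of high local Saa3 share (camera adjusted p = 8.5e-07 at the preset correlation; over all spots, adjusted p = 0.919 with an estimated correlation). The spots of high local Saa3 share held 53.8% of Col1a1 UMIs in the Hk2-deleted section against 29.4% and 18.7% in fibrotic replicates 1 and 2. Their removal could therefore by itself lower the matrix median of the Hk2-deleted section. In the extracellular vesicle list 0 of 38 passed (0 adjusted over the list alone), with a median of -0.02. In the stress list 1 of 19 rose, Mt2 (2 adjusted over the list alone), and the platelet gene Ppbp rose by 1.06 ± 0.20 as 1 of 9 markers of other tissue or blood (2 higher and 3 lower adjusted over the list alone). None of the 24 stellate genes passed (1 each way adjusted over the list alone), with a median of -0.10 and a mean of 0.01, and no member of the other lists passed over all genes. The Hk2-deleted section also had 31.0% of its spots next to or holding a UMI of the mesothelial markers Msln or Upk3b, against 33.3% and 2.29% in the fibrotic sections.

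In all, 20 genes rose and 12 fell of 14125 tested (443 had an unadjusted p under 0.05), and each of the 32 had the same sign against either fibrotic section alone. Among the genes called, without fibrotic replicate 1, Mmp12 was at -0.91 and Ighg2c at -1.28, and without replicate 2, Ppp1r3g was at -1.15. DESeq2 called 11 higher and 10 lower and did not call Saa3, Lcn2, Angptl8, Ighg2c, Mmp12, Ppbp or Ppp1r3g, and without the filter on low counts 69 rose and 57 fell. Saa3 and Lcn2 also differed between the fibrotic sections, with normalised levels of 20.1 and 3.64 CPM for Saa3 and 106 and 255 CPM for Lcn2, against 136 and 776 CPM in the Hk2-deleted section.

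**Figure D3:**
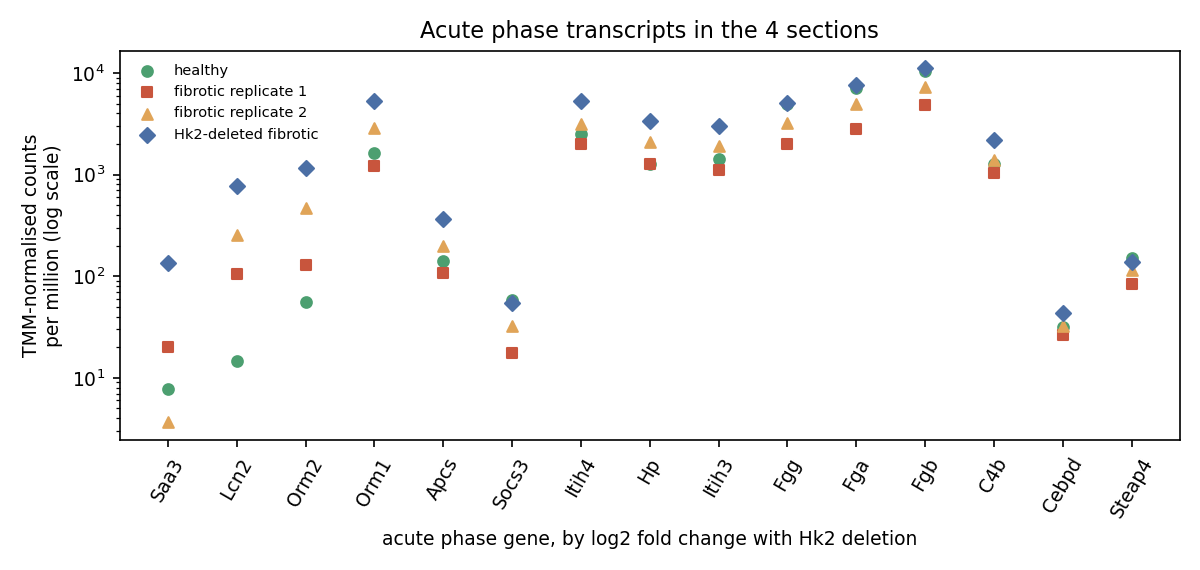
TMM-normalised CPM (vertical axis, log scale) of 15 acute phase genes (horizontal axis, ordered by log2 fold change with Hk2 deletion), with a point per section. Saa3 is at 136 CPM in the Hk2-deleted section and at 20.1 and 3.64 CPM in the fibrotic sections.

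Whether Hk2 deletion moved genes back toward the healthy state was asked by the agreement of both contrasts across genes, which are not independent replicates. Pearson's r over 14125 genes was -0.117 (covariance -0.043), and simulations without any effect, in which both contrasts share the fibrotic sections, gave a mean of -0.336 (covariance -0.0599). The simulations held no effect of CCl4 either, so their r is not what the shared sections alone would give in these data. With a different fibrotic section in each contrast, r was 0.237 with replicate 1 and -0.147 with replicate 2 in the CCl4 contrast. Among the 1929 genes called for CCl4, which were chosen with the same sections, r was -0.165 with shared sections. With a different section in each contrast it was 0.152 and -0.237 in the same order. The direction thus depended on the section used, and no return toward the healthy state was detectable.

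Pericentral against periportal spots asks where in the lobule transcripts lay, over 4 sections. Around the central vein, the Wnt agonist Rspo3 (1.76 ± 0.10 log2), the transcription factor Tbx3 (1.68 ± 0.13), the dicarboxylate transporter Slc13a3 (1.99 ± 0.14), Lhpp (1.83 ± 0.16) and the glutathione transferase Gstm3 (1.75 ± 0.10) were higher. Ighg2c (1.99 ± 0.26), Mmp12 (1.71 ± 0.11) and the protease inhibitor Slpi (1.64 ± 0.22) were higher there as well. Toward the portal vein Hsd17b6 (-1.95 ± 0.11), Cyp17a1 (-1.77 ± 0.09), Clec2h (-1.73 ± 0.11), Sdsl (-1.68 ± 0.13), Bdh2 (-1.55 ± 0.12), the glycine decarboxylase Gldc (-1.48 ± 0.11), the macrophage scavenger receptor Marco (-1.44 ± 0.11) and Tiam2 (-1.42 ± 0.16) were higher. Of the genes that defined the zones, Cyp2e1 was at 1.41 and Cyp2f2 at -2.01. Hk2 was at 0.44 ± 0.25 (adjusted p = 0.298), at 0.69 and called without the healthy section (adjusted p = 0.0023), and at 0.20 without the Hk2-deleted section (adjusted p = 0.778).

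Other pericentral hepatocyte genes had 16 of 22 higher (17 adjusted over the list alone; Lgr5 2.07) and other periportal genes 18 of 22 lower (19 adjusted over the list alone; Ftcd -1.26). Pericentral spots had 15 of 36 other extracellular matrix genes higher and 1 lower (27 and 2 adjusted over the list alone; Ltbp2 2.1), all 3 fibrillar collagens (Col1a1 1.27 ± 0.28, adjusted p = 0.031). In the healthy section the log2 ratio was -0.31 for Col1a1, -0.16 for Col3a1 and 0.05 for Col1a2, against at least 1.02 in the CCl4-treated sections. Over the 4 sections, pericentral spots also had higher levels of 7 of 24 stellate genes (8 higher and 3 lower adjusted over the list alone) and 11 of 24 lymphocyte and neutrophil genes (15 adjusted over the list alone; Jchain 1.30). Macrophage genes had 5 of 24 higher (Gpnmb 1.81, Trem2 1.53) and 4 lower (9 and 4 adjusted over the list alone). Lower were 9 of 15 acute phase genes, with 1 higher (10 and 2 adjusted over the list alone, with Orm1 at -0.83). So were 6 of 13 genes of hepatocyte glucose metabolism (9 lower and 1 higher adjusted over the list alone). Pck1 (-1.22), a landmark that defined the zones, was left out of these 13. Also lower were 6 of 13 cholangiocyte genes (6 adjusted over the list alone, with Spp1 at -1.19). Camera called these lists (adjusted p from 5.8e-28 to 0.0216), and none kept the call (adjusted p of 0.297 to 0.841 with an estimated correlation). In the glycolysis list of 17, Pfkfb3 was higher (0.65) and Pgk1 lower (-0.32; 4 and 1 adjusted over the list alone). In the vesicle list 2 of 38 were higher and 1 lower (0 and 1 adjusted over the list alone; Cd63 0.88, Sdc1 -0.66), and its median of 0.00 was positive while camera pointed down (adjusted p = 0.862). Wt1 was higher by 1.84. Gpnmb (-0.65) and Cd63 (-1.09) also had the opposite sign in the healthy section. Both were scarce there, at 0.222 and 1.73 normalised CPM over the whole section, so these signs rest on few UMIs. In all, 761 genes were higher and 681 lower of 13079 tested. Without the healthy section these counts were 2681 and 2832, and without fibrotic replicate 1, fibrotic replicate 2 or the Hk2-deleted section they were 127 and 111, 120 and 103, or 86 and 91. Col1a1, Col1a2, Col3a1, Orm1, Cd63, Pfkfb3, Pgk1 and the landmark Pck1 lost their call whichever of these 3 CCl4-treated sections was left out. Median UMIs per spot also differed between the zones, at 11812 pericentral and 19851 periportal in the healthy section and 17596.5 and 12333 in fibrotic replicate 1.

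Zonation under CCl4 asks whether the difference between zones differed between fibrotic (n = 2) and healthy (n = 1) sections. Some landmarks of the zone score changed with CCl4 themselves. In whole sections Oat (-2.82) and Slc1a2 (-2.73) were lower, and Axin2 (1.30), Rhbg (1.31), Aldh1b1 (1.49) and Ctsc (0.95) higher. The spots called pericentral may therefore not be the same region in healthy and CCl4-treated sections. Genes of stellate cells and macrophages shifted toward pericentral spots with CCl4: Pdgfrb by 2.06 ± 0.22 log2 (adjusted p = 4.3e-07), the macrophage genes Ms4a7 (2.84 ± 0.38) and Lgals3 (1.32), and the matrix genes Adamts12 (2.59 ± 0.47), Svep1 (2.39 ± 0.36) and Col1a1 (1.70 ± 0.23). Gpx3 (2.55 ± 0.20), Dpep1 (2.44 ± 0.34), Retnlg (2.26 ± 0.67), Plagl1 (2.07 ± 0.37) and Cd34 (2.07 ± 0.33) shifted the same way. Toward periportal spots shifted Cyp2b13 (-2.38 ± 0.46), Cyp2a4 (-1.95 ± 0.33), Slc22a26 (-1.93 ± 0.19), Orm3 (-1.89 ± 0.14), the retinol dehydrogenase Rdh16 (-1.73 ± 0.10), Gstt3 (-1.62 ± 0.12), Mup17 (-1.47 ± 0.11) and the hepcidin Hamp2 (-1.46 ± 0.11). Cyp2b13 was at 38.3 CPM in fibrotic replicate 1, which lacked Y-linked transcripts, and at 0.271 CPM in fibrotic replicate 2, and the shift of Cyp2a4 was -0.48 without replicate 1. Hk2 shifted toward pericentral spots by 1.36 ± 0.42 (adjusted p = 0.025): its pericentral to periportal log2 ratio was -0.82 in the healthy section, 0.49 and 0.59 in the fibrotic sections and 1.00 in the Hk2-deleted section.

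The glycolysis list had 5 of 17 members shifted to pericentral and 1 to periportal spots (the same adjusted over the list alone), Hk3 by 0.92, Pkm by 0.74 and Pfkp by 0.78. For this list camera gave adjusted p = 0.0454, and adjusted p = 0.542 with an estimated correlation. Shifted to pericentral spots were 25 of 36 other extracellular matrix genes (26 adjusted over the list alone), all 3 fibrillar collagens and 18 of 24 stellate genes with 1 the other way (19 and 1 adjusted over the list alone). The same held for 16 of 24 macrophage genes with 1 the other way (16 and 1 adjusted over the list alone), 9 of 24 lymphocyte and neutrophil genes (10 adjusted over the list alone) and 7 of 13 cholangiocyte genes (8 adjusted over the list alone). Shifted to periportal spots were 11 of 16 fatty acid oxidation genes (14 adjusted over the list alone; Acaa1b -0.82) and 10 of 16 cytochrome P450 genes with 2 the other way (10 and 2 adjusted over the list alone; Cyp4a10 -1.07). So were 11 of 22 other pericentral genes (13 adjusted over the list alone; Hpd -1.01) and 15 of 22 other periportal genes with 2 the other way (15 and 2 adjusted over the list alone; Serpina1c -0.89). These 9 lists were called by camera (adjusted p from 1.8e-27 to 8.7e-05), and none kept the call (adjusted p of 0.542 to 0.698 with an estimated correlation). The other pericentral and the other periportal list thus shifted the same way. In the vesicle list 3 of 38 shifted each way (2 and 3 adjusted over the list alone; Cd63 2.02, Sdcbp 0.63, Sdc4 -0.53), with a median of -0.04 and a mean of 0.03. In all, 1144 genes shifted to pericentral and 1455 to periportal spots of 13332 tested. DESeq2 called 164 and 179, without Cd63, Hk3, Pfkp, Pkm, Cyp2a4 and Retnlg and with no adjusted p for Hk2. With the top and bottom of 5 equal parts of spots 673 and 902 were called and Hk2 was not (1.36, adjusted p = 0.114); Pkm, Pfkp, Cd63 and Retnlg were not called there either. The contrast rests on 1 healthy section.

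Collagen-high against other spots asks which genes lay with fibrosis within the 3 CCl4-treated sections. Hk2 was higher in collagen-high spots by 0.84 ± 0.17 log2 (adjusted p = 0.00097), as were Hk1 (0.62 ± 0.08) and Hk3 (0.37 ± 0.10). Among the larger increases were the matrix genes Mfap4 (2.03 ± 0.13), the crosslinking enzyme Loxl1 (1.94 ± 0.13), Dpt (1.85 ± 0.11) and elastin Eln (1.82 ± 0.11). Slpi (2.25 ± 0.14), Dpep1 (1.89 ± 0.12), the prostacyclin synthase Ptgis (1.79 ± 0.17) and the keratin Krt7 (1.85 ± 0.18) were among them too. Lower were the amino acid enzymes Hal (-1.49 ± 0.07), Sds (-1.40 ± 0.07), Etnppl (-1.40 ± 0.07) and Gls2 (-1.31 ± 0.07), with Cyp2f2 (-1.39 ± 0.07), Tiam2 (-1.32 ± 0.14), Marco (-1.28 ± 0.08) and Cyp17a1 (-1.27 ± 0.10). Msln (2.58 ± 0.17) and Upk3b (2.57 ± 0.28), markers of the liver's mesothelial surface, and Wt1 (2.13 ± 0.22) were higher in the same spots. In fibrotic replicate 2, 2.29% of spots held or bordered a Msln or Upk3b UMI, so the rise of both rests mainly on the other sections. Wt1 had a collagen-high to other log2 ratio of 1.90 in that section too, so it need not mark surface tissue. The ratio of Krt7 was 0.54 there, against 1.755 in fibrotic replicate 1 and 2.346 in the Hk2-deleted section. For the keratin Krt19 it was 0.32, 1.557 and 2.36 in the same order. Whether these keratins mark ducts or surface tissue was not tested.

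Of 36 other extracellular matrix genes 34 were higher and 1 lower (34 and 1 adjusted over the list alone; Ltbp2 2.47, Lox 2.32, Timp1 2.27), and of 24 stellate genes 23 were higher (23 adjusted over the list alone; Pdgfrb 1.39 ± 0.07, Acta2 1.42 ± 0.12). The glycolysis list had 8 of 17 higher and 2 lower (8 and 2 adjusted over the list alone), with Slc16a3 at 1.23, Pfkp at 0.92 and Pkm at 0.74 (camera adjusted p = 0.0654). Vesicle genes went both ways, 8 of 38 higher and 8 lower (8 and 9 adjusted over the list alone), with Cd63 at 0.93, Rab27b at 0.80, Rab27a at 0.49 and Sdc1 at -0.68 (camera adjusted p = 0.962), with a median just below 0 and a mean of 0.04. Higher were also 15 of 24 macrophage genes with 3 lower (15 and 3 adjusted over the list alone; Itgam 1.09), 17 of 24 lymphocyte and neutrophil genes (18 adjusted over the list alone; Ly6g 1.35) and 8 of 14 cholangiocyte genes with 1 lower (9 and 1 adjusted over the list alone; Krt19 1.75). Lower were all 14 genes of hepatocyte glucose metabolism (14 adjusted over the list alone; Pck1 -1.13, Fbp1 -0.93), 21 of 22 other periportal genes (21 adjusted over the list alone), 14 of 16 fatty acid oxidation genes (15 adjusted over the list alone). So were 10 of 15 acute phase genes with 2 higher (10 and 3 adjusted over the list alone; Orm1 -0.97, Saa3 2.49) and 8 of 14 lipogenesis genes (9 adjusted over the list alone). The matrix, stellate, macrophage, lymphocyte, cholangiocyte, glucose, periportal, fatty acid, acute phase and lipogenesis lists were called by camera (adjusted p from 2.3e-44 to 0.0064), and none kept the call (adjusted p of 0.179 to 0.517 with an estimated correlation). In all, 2929 genes were higher and 2963 lower of 13493 tested, and DESeq2 called 1899 higher and did not call Saa3. Hk3 was not called without fibrotic replicate 2, with the top 5 percent of spots, or without spots near Msln or Upk3b UMIs, where Slc16a3 was not called either and Saa3 was at 0.84. Without the Hk2-deleted section, Lox was at 1.44, Timp1 at 1.44 and Saa3 at 1.55.

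Collagen-high spots with Hk2 deletion asks whether these spots differed between the Hk2-deleted (n = 1) and fibrotic sections (n = 2). The contrast of collagen-high with other spots was larger in the Hk2-deleted section for Timp1 (1.79 ± 0.43 log2), Lox (2.01 ± 0.50), Saa3 (1.73 ± 0.12), Ptgis (1.13 ± 0.13), Gas1 (1.09 ± 0.15), Cd14 (1.06 ± 0.21), the zinc transporter Slc39a8 (1.04 ± 0.15), Crip1 (1.01 ± 0.10), Ezr (0.97 ± 0.15) and Efemp1 (0.92 ± 0.16). It was smaller for Ighg2c (-2.31 ± 0.13), Adam23 (-0.92 ± 0.20), Ighj4 (-0.86 ± 0.10), Cep85l (-0.70 ± 0.16), Rfesd (-0.69 ± 0.19), Lcn2 (-0.60 ± 0.11), Ell (-0.57 ± 0.14) and Pcnp (-0.50 ± 0.14). The fit had 1 residual degree of freedom and took its variance from the trend over all genes. These SEs thus do not measure how single genes vary between mice. The collagen-high to other log2 ratios of fibrotic replicates 1 and 2 were 1.80 and -0.28 for Saa3 and 1.19 and 0.37 for Gas1. Col1a1 was at 1.13 ± 0.11, but it helped define the spots, so its contrast depends on how they were chosen. Hk2 itself did not differ detectably (-0.01 ± 0.36, adjusted p = 0.997). Wt1 (1.10) and the keratins Krt19 (1.08) and Krt7 (0.90) had a larger contrast too. The other 12 of 14 cholangiocyte genes did not pass (2 larger and 1 smaller adjusted over the list alone), and the list's median was -0.21 (camera adjusted p = 0.293). In all, 66.1% of collagen-high spots held or bordered a spot with a Msln or Upk3b UMI in the Hk2-deleted section against 49.2% and 2.33% in the fibrotic sections.

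Of 36 other extracellular matrix genes 18 had a larger contrast (25 adjusted over the list alone, with 1 smaller; median 0.44), as had 6 of 24 stellate genes (8 adjusted over the list alone; Cygb 0.76, S100a6 0.72). The macrophage list had 2 of 24 smaller (9 adjusted over the list alone; Vsig4 -0.43, Cd5l -0.40), and fatty acid oxidation had 2 of 16 larger (3 adjusted over the list alone; Acaa1b 0.42). Camera called these 4 lists (adjusted p from 2.3e-23 to 7.8e-06), each with adjusted p = 0.80 with an estimated correlation. It also called the list of tissue or blood other than liver parenchyma, with 3 of 9 larger (4 and 2 smaller adjusted over the list alone; Wt1 1.10, Ppbp 0.89, Pf4 0.88), and 7 lists with at most 1 member passing. For these 8 lists adjusted p was from 0.00075 to 0.0381, and none kept the call either (adjusted p = 0.80 with an estimated correlation). In the glycolysis list 1 of 17 was larger, Pkm (0.46), and in the vesicle list 1 of 38, Arf6 (0.36), with the same counts adjusted over each list alone. In all, 152 genes had a larger and 23 a smaller contrast of 13954 tested (1266 had an unadjusted p under 0.05). This comparison was the least stable: DESeq2 called 3 and 2, and without spots near Msln or Upk3b UMIs 5 and 4 were called, Timp1 (0.50) was not, and Col1a1 was at 0.34. Without spots of few UMIs the counts were 50 and 4, with the top 20 percent of spots 62 and 6, and with RLE size factors 13 were smaller. Timp1 was not called in the former 2 of these settings, nor with the top 5 percent of spots. Without fibrotic replicate 1, Saa3 was at 3.61, Gas1 at 1.68, Krt19 at 2.04 and Krt7 at 1.81, and without replicate 2, Krt7 was at 0.55.

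Across spots within a section, glycolysis and fibrillar collagen shares had a Spearman correlation of 0.00551 in the healthy section, 0.237 and 0.216 in the fibrotic sections and 0.189 in the Hk2-deleted section. Extracellular vesicle and collagen shares had 0.0509, 0.276, 0.244 and 0.170, and vesicle and glycolysis shares 0.0111, 0.121, 0.125 and 0.119, in the same order. The healthy section held 3285 fibrillar collagen UMIs over 3064 spots, 1191 of them in its 306 collagen-high spots. Counting error thus presses its correlations with collagen toward 0. Random lists in place of glycolysis had a central 95% of -0.040 to 0.070 there and of -0.071 to 0.385 in fibrotic replicate 1. None of these 12 values lay outside the central 95% of random lists with matched expression; the highest percentile was 96.9, for vesicle with glycolysis shares in the Hk2-deleted section. Glycolysis transcripts were at 1055 CPM in collagen-high spots and 799 CPM at 4 or more array steps away in fibrotic replicate 1, at 959 and 763 CPM in fibrotic replicate 2, at 1017 and 736 CPM in the Hk2-deleted section and at 632 and 598 CPM in the healthy section. In the same order, vesicle transcripts were at 4200 and 3638 CPM, 4318 and 3740 CPM, 4414 and 3807 CPM, and 3428 and 3375 CPM, and Hk2 was at 9.65 and 4.01 CPM, 7.65 and 3.19 CPM, 7.06 and 2.65 CPM, and 2.14 and 1.99 CPM, from 73, 27, 44 and 10 UMIs in the collagen-high spots.

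**Figure D4:**
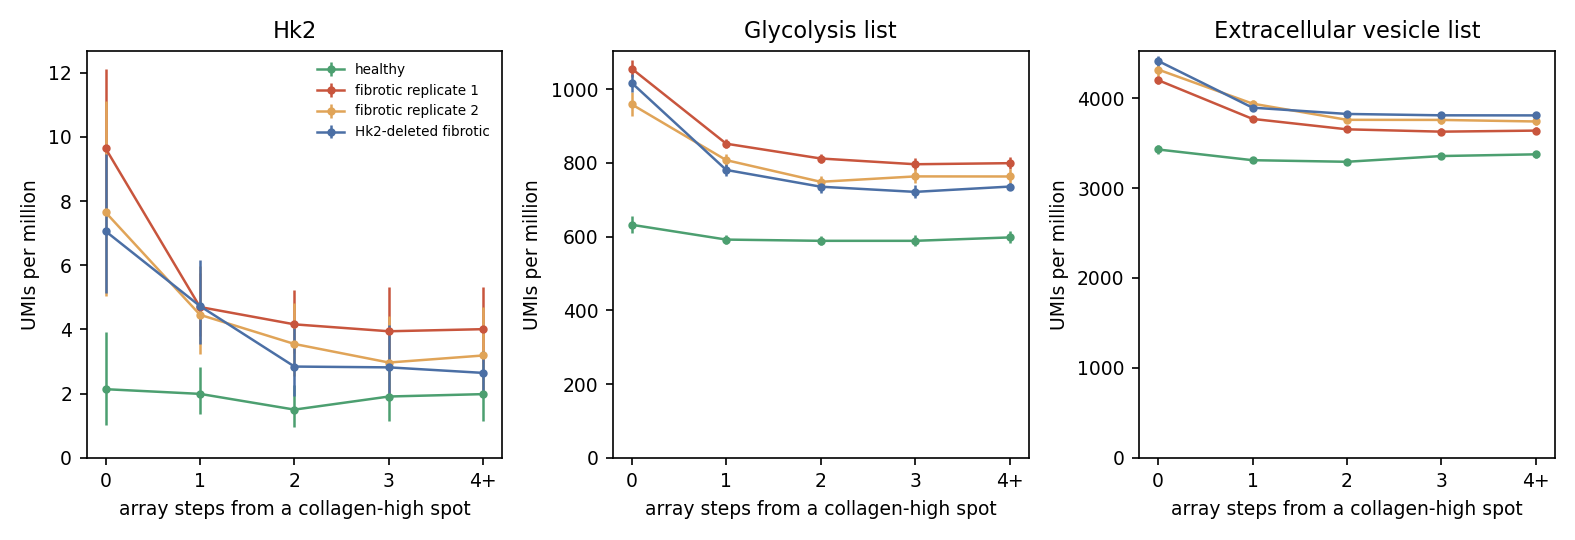
Raw CPM (vertical axes) of Hk2, the glycolysis list and the extracellular vesicle list by array steps from the nearest collagen-high spot (horizontal axes), with a line per section and exact Poisson 95% intervals. In the CCl4-treated sections each is highest in the collagen-high spots themselves, at 9.65, 7.65 and 7.06 CPM for Hk2.

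In the authors' deposited table, Moran's I, which is high where neighbouring spots have like levels, was 0.641 for Saa3 in the Hk2-deleted section, the highest of its 17028 genes, against 0.186 and 0.00429 in the fibrotic sections and 0.0661 in the healthy section. Col1a1 had a Moran's I of 0.391 in the Hk2-deleted section, 0.242 and 0.224 in the fibrotic sections and 0.0368 in the healthy section in the authors' deposited table. The healthy section held 423 Col1a1 UMIs in all, so its value is limited by counts. The glycolysis list had a median Moran's I between 0.00251 and 0.0127 in the authors' deposited table.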

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

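Chosen only after the result was seen were the tests of loss of the Y chromosome, of Hk2 in collagen-high spots and of variation between the fibrotic sections, and the removal of collagen-matched spots. The fits without spots near Msln or Upk3b UMIs and without spots of high local Saa3 share were also added after seeing the data.

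The difference between pericentral and periportal spots differed between fibrotic and healthy sections by a test of the difference itself, for 1144 genes toward pericentral and 1455 toward periportal spots. Among the genes that could be named in any comparison, Pdgfrb differed by 2.06 log2, Col1a1 by 1.70, Hk2 by 1.36, Hk3 by 0.92 and Cyp2f2 by 0.38; Cyp2f2 is a landmark of the zone score, so its value depends on how the zones were drawn, and it was 0.14 without fibrotic replicate 1 and 0.62 without replicate 2. The contrast of collagen-high with other spots differed with Hk2 deletion for 152 genes upward and 23 downward, with Timp1 at 1.79. Col1a1, at 1.13, helped define the spots and is not among these genes. Each of these differences rests on a lone section in 1 of its groups. Some landmarks of the zone score changed with CCl4 themselves, so the zones may not match between healthy and CCl4-treated sections.

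Fibrotic replicate 1 had Uty at 0.163 CPM and Kdm5d at 0.0741 CPM, against at least 14.5 CPM of either in each other section. Loss of the Y chromosome in a male mouse is argued against by 5 female-biased liver genes: their median log2 ratio over the higher of the other 2 CCl4-treated sections was 2.96. A section from a female mouse, which the label does not give, may explain the levels, since 4 X-linked genes that escape inactivation had a median log2 ratio of 0.45 over the other sections (0.20 to 0.62). Whether the label or the section was exchanged stays open. Sex is thus a possible difference between the fibrotic sections in every comparison that uses both, and its effect was not tested apart from the section.

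All 15 acute phase genes had a positive fold change with Hk2 deletion. The median was 0.99 log2 with RLE size factors against 1.00 with TMM. Both give 1 factor per library on the assumption that most genes do not change, so their agreement cannot decide on scaling. A single focus of Saa3 is argued against for the other 14 genes, whose median was 1.05 without the spots of highest local Saa3 share against 0.99 over all spots. Variation between sections stays open, since the fibrotic sections differed from each other by a median absolute log2 ratio of 0.79 over the list (0.31 to 2.46). With 1 Hk2-deleted section, an effect of genotype and variation between mice cannot be told apart.

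Of 36 extracellular matrix genes, 18 had a larger contrast of collagen-high spots in the Hk2-deleted section, with a median difference of 0.44 log2 over the list, 5 members below 0 and adjusted p = 0.80 with an estimated correlation. Without spots near Msln or Upk3b UMIs the median was 0.15 (members from -2.02 to 0.83), so surface tissue among the collagen-high spots could contribute. That removal takes many collagen-high spots with it, and 10 removals of collagen-matched spots gave medians of 0.0608 to 0.397, a range that holds 0.15, with 4 to 86 genes larger and 1 to 14 smaller. The test therefore decides nothing, and neither does the median absolute difference of 0.21 between the fibrotic sections (0.02 to 1.04). Surface tissue, variation between sections and genotype cannot be told apart.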

How the results depend on the processing

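The comparisons without spots near Msln or Upk3b UMIs, without spots of high local Saa3 share, with the 2 CCl4 sections that have Y-linked transcripts, and with all 3 CCl4 sections for the whole-section contrast were chosen after seeing the data. Over all alternatives, 253 values that summarise a comparison were unchanged, 73 moved, 13 reversed, 20 lost and 4 gained a call. For named genes these numbers were 3699, 172, 21, 441 and 20. For tested values, unchanged means the same direction and side of the threshold. For gene counts it means a count within a fixed ratio of the main one. For values without a test it means a shift within an SE or within the spread of the fibrotic sections. The cause was not tested for any value given here, except where the setting itself uses fewer spots or sections. No paired analysis was possible because each section came from a different mouse, so groups were not paired; zones and kinds of spot were compared within sections. Leaving out a fibrotic section leaves no residual degree of freedom in the whole-section and interaction fits, so those values carry no test. DESeq2 gave no adjusted p for 11 named genes of zonation under CCl4 and 14 of collagen-high spots with Hk2 deletion. Depth limits genes with few UMIs, such as Hk2 with 100 to 329 per section and Timp1 with 8 to 172.

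DESeq2 called 729 genes higher and 295 lower for CCl4, 11 higher for Hk2 deletion, 164 and 179 for zonation under CCl4, 1899 higher for collagen-high spots, and 3 and 2 for collagen-high spots with Hk2 deletion; it put the glycolysis median of zonation under CCl4 at 0.29 (adjusted p = 0.0675). RLE size factors gave 0.29 there (adjusted p = 0.0502) and 13 genes lower for collagen-high spots with Hk2 deletion. Without a filter on low counts, 69 genes were higher and 57 lower for Hk2 deletion. The glycolysis median of collagen-high spots was 0.28 there and passed by camera at the preset correlation (adjusted p = 0.0353). An estimated correlation was not tried in that setting. Equal weight per spot with limma called 204 genes lower for CCl4. It put the vesicle median at 0.20 for CCl4 and, for Hk2 deletion, the matrix median at 0.051, the vesicle median at 0.028 and Cyp2e1 at 0.093, all reversed in sign. Thinning to the smallest total gave, for Hk2 deletion, a glycolysis median of -0.14 (adjusted p = 0.0552) and a vesicle median of 0.012.

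With an estimated correlation or fry, the medians are the same and the calls ended, for the matrix list at 1.91 (CCl4; adjusted p = 0.562 and 0.324), 0.78 (zones; 0.627 and 0.293), 1.08 (zonation under CCl4; 0.542 and 0.202) and 0.44 (collagen-high spots with Hk2 deletion; 0.80 and 0.814). With 1 to 3 residual degrees of freedom, the test with an estimated correlation could hardly call any list. For collagen-high spots the matrix list at 1.2 lost its call with an estimated correlation alone (0.179). The glycolysis list lost it at -0.16 (Hk2 deletion; 0.919 and 0.956) and 0.30 (zonation under CCl4; 0.542 and 0.126), and the acute phase list at 1.00 (Hk2 deletion; 0.919 and 0.956).

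The top and bottom of 5 equal parts of spots put the vesicle median between zones at -0.0090 and, for zonation under CCl4, gave 673 and 902 genes, a glycolysis median of 0.26 (adjusted p = 0.160) and Acta2 at -0.37. A log ratio of landmark counts gave 0.26 for glycolysis (adjusted p = 0.114). The top 5 percent of spots gave a glycolysis median of 0.32 for collagen-high spots (camera adjusted p = 0.0457 at the preset correlation, with no estimated correlation tried). The vesicle median was 0.061 there, and Hk2 was at 0.0069 with Hk2 deletion. The top 20 percent gave, with Hk2 deletion, 62 and 6 genes, a vesicle median of -0.039, Cyp2e1 at -0.027, Cyp2f2 at 0.093, Hk2 at 0.060 and Hk3 at -0.082. Without spots of few UMIs, collagen-high spots with Hk2 deletion had 50 and 4 genes and a vesicle median of -0.0043.

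With the 2 CCl4 sections that have Y-linked transcripts, Cyp2f2 was at -0.074 for CCl4, and with all 3 CCl4 sections Cyp2f2 was at -0.039 for CCl4. Without spots of high local Saa3 share, Hk2 deletion gave 32 and 28 genes, a matrix median of -0.32 that passed at the preset correlation (adjusted p = 8.5e-07; over all spots, 0.919 with an estimated correlation) and Timp1 at -0.21. That removal took a larger share of Col1a1 UMIs from the Hk2-deleted section than from the fibrotic ones. It could therefore by itself lower the matrix median. Without spots near Msln or Upk3b UMIs, collagen-high spots with Hk2 deletion gave 5 and 4 genes, a glycolysis median of -0.035 and a vesicle median of -0.080. Reversed there were Arf6 (-0.035), Cd14 (-0.11), Cyp2f2 (0.15), Hk1 (-0.038), Hk2 (0.20), Hk3 (-0.16), Krt7 (-0.11), Pf4 (-0.14), Ppbp (-0.25), S100a8 (-0.097) and S100a9 (-0.042).

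Leaving out 1 section at a time gave, for CCl4, 0.10 to 0.26 for the glycolysis median and -0.21 to 0.0028 for the vesicle median. It gave -0.20 to -0.18 for the glycolysis median and -0.29 to 0.19 for the matrix median of Hk2 deletion, 86 to 2681 genes higher and 91 to 2832 lower between zones with a vesicle median of -0.0064 to 0.010, and 0.27 to 0.29 for glycolysis and -0.048 to -0.020 for vesicles in zonation under CCl4. Collagen-high spots gave 0.19 to 0.26 for glycolysis and -0.047 to 0.014 for vesicles. With Hk2 deletion they gave 0.34 to 0.45 for the matrix list, -0.0045 to 0.15 for glycolysis and -0.0038 to 0.0025 for vesicles.

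Unthinned shares of all spots gave correlations of glycolysis with collagen of 0.0478 (healthy), 0.299 and 0.258 (fibrotic replicates 1 and 2) and 0.234 (Hk2-deleted), and of vesicles with collagen of 0.341, 0.308 and 0.209 in the CCl4 sections. For vesicles with glycolysis they gave 0.00095, 0.189, 0.171 and 0.158. Pearson's r on log2(CPM + 1) gave -0.0203, 0.185, 0.147 and 0.126 for glycolysis with collagen, 0.179 for vesicles with collagen in fibrotic replicate 2, and 0.125, 0.118 and 0.106 for vesicles with glycolysis in the CCl4 sections. The log2 ratio of glycolysis in collagen-high spots over spots 4 or more steps away was 0.47, 0.43 and 0.62 in the CCl4 sections with the top 5 percent of spots and 0.29, 0.25 and 0.32 with the top 20 percent. For vesicles it was 0.036, 0.28, 0.24 and 0.32 in the 4 sections with the top 5 percent and -0.021, 0.16, 0.17 and 0.13 with the top 20 percent. The correlation of the whole-section contrasts was 0.237 and -0.147 with a different fibrotic section in each.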

Other observations

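The test of Hk2 in collagen-high spots was chosen only after the Hk2 level of the Hk2-deleted section was seen.

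Hk2 signal from cells other than stellate cells might hide a loss in stellate cells. If so, Hk2 would lie less in collagen-high spots of the Hk2-deleted section, and the difference in its log2 ratio was -0.013 with an interval of -0.73 to 0.71. Counts of Hk2 were too few to decide.

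Swaps of the zone labels within sections were too few for a share under 0.05: the real labels called 1442 genes and the highest of the other swaps, that of the healthy section, 1186, and 1 of 8 arrangements called as many as the real one. Swaps of the collagen-high labels were also too few, with 5892 genes for the real labels, 0 for the highest other and 1 of 4 arrangements with as many.

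In the Hk2-deleted section, the spots with the highest local Saa3 share (773 spots) held 85.1% of Saa3 UMIs. Saa3 was at 698 CPM inside and 26.9 CPM outside, Msln at 32.0 and 1.61 CPM, Krt7 at 48.4 and 8.01 CPM and Col1a1 at 763 and 144 CPM. Lcn2, at 815 and 853 CPM, and Cxcl1, at 91.5 and 121 CPM, were not higher inside, while Hp, at 4271 and 3544 CPM, was. These spots were defined by Saa3, and 26.6% of them were collagen-high.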
